A study of Homo sapiens with 6 samples.

How the data were processed

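Expression was measured in RWPE-1 cells given LNA-205 or LNA-Scr, with 3 arrays per group. Groups and replicate letters were taken from the sample titles. The letters A to F are not shared between groups, so nothing pairs the samples and no block was fitted. Per the labels, RNA was extracted with Trizol and cleaned on RNeasy columns with DNase treatment, and biotinylated cRNA was made with the Illumina TotalPrep kit.

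The deposited unnormalized values are log2 values of probe intensities: 2 to the power of each value lies within 0.000248 of a number with 1 decimal, as scanner software exports intensities. No background had been subtracted and no normalization between arrays had been applied, as judged from the values. The deposited detection p-values, 1 column per sample per the file headers, compare a probe with the negative control beads of its array. Each was assigned to the sample column at its left, and its Spearman correlation with that array's intensity was between −0.998 and −0.994. The authors' processed log2 values, used as an alternative, are an order-keeping function of each array's unnormalized values (Spearman correlation 1), and those of LNA-205 replicate E are identical to its unnormalized values for all 48799 probes, as if it had been the reference array. The method of that normalization is not given in the sources used here. The lumi package, without a version or a role, is named per the submitters' processing notes.

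Of 48803 probe rows, 4 held no values, and 48799 were used. Background was corrected with limma's neqc, which fits a normal plus exponential model with the mean and SD of the negative controls inferred from the detection p-values, adds an offset of 16, quantile normalizes and takes log2. Probes were kept where the detection p was under 0.01 on at least 3 of the 6 arrays, whatever their group. This left 13423 probes (27.5%). Probes were named from a platform annotation table, in which 28095 probes had 1 gene symbol, 13 had several and 20691 were not listed. Symbols were updated through gene identifiers with a RefSeq gene table of GRCh38.p14 for 28056 probes, and no coordinates were taken from it because the array files name no genome build. For each gene the probe with the highest mean over the 6 arrays was used, and other kept probes stayed as their own feature, which gave 10803 features (8952 genes and 1851 unnamed probes). Where a gene has several detected probes that differ in sign, the text gives both.

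Features were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the 10803 features and a threshold of 0.05. A negative log2 difference means a lower value in LNA-205. For a probe not above background on any array of a group, a fold is a lower bound: the mean of the brighter group against the mean, per array, of the higher of the probe's own value and the lowest value among probes above background. Before the data were examined, 23 gene lists were fixed from textbook knowledge, with 521 entries. The 20 lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over these lists. Beside it, camera with an estimated correlation called 0 of the 20 lists, and fry called 2, the squamous differentiation and basal epithelial lists. Array means of lists were compared with two-sided exact permutation tests.

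The genes named in the text follow a rule fixed before the data were examined. It takes the 12 genes per direction with the largest difference among those past the threshold without overlap, or, where fewer than 5 pass, the 5 with the smallest p. It adds, from each list, up to 4 called members and the 2 brightest members that were not called, and 25 genes always named where measured. Some brightest members are left out where the list's count says enough. Members of the squamous list other than KRT10, PI3 and KLK5 were named after their values were seen, as were RSAD2, IFIT5, TIMP2, MMP14, MED1, LYN, ITGA5, BCL2L2, TM7SF2, KRT16 and TRIM29 and the genes named in the closing observations.

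The fits were tested on simulated data, with 200 of the 10803 features changed in each of 20 simulations. Variances were drawn at random from the distribution limma fitted to these arrays, without a link to intensity, and noise was normal. The simulated data thus meet the assumptions of the test, and the rates may be better than in real data. Genes changed by log2 values of 0.5, 1, 1.5 and 2 were called in 15.6%, 86.6%, 97% and 99.1% of cases, and 4.84% of called genes were false. Simulated lists of 14 genes shifted by 0.3 were called in 100% of cases by camera with the preset correlation and in 30% with an estimated one, and lists shifted by 0.5 in 100% and 90%. Unshifted lists were called in 0.588% of cases with the preset correlation. Simulated genes were independent of each other, so these rates leave out correlation between genes. Calls of single genes also depend on how many features change, and the rates given hold for 200.

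The alternatives were no background correction, normexp without detection p-values (offset 50), the authors' processed values, cyclic loess or median scaling in place of quantile normalization, no detection filter, detection on all 6 arrays, the mean of a gene's probes, every probe as its own feature, eBayes with trend and robust, array weights, each array left out in turn, a minimum log2 difference of 1, an adjusted p under 0.01, camera with an estimated correlation, and fry. A planned test of miR-205 seed matches in 3′ untranslated regions was not run, because no transcript sequences were used here. The slide as a block was not run, because the column names do not give the slide. TP63 had no probe named in the table used here and was not analysed.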

Results

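Gene expression was measured in RWPE-1 cells, an immortalised but non-tumorigenic line of human prostate epithelial cells, 72 h after transfection with 100 nM of either of 2 oligomers. LNA-205 is an antisense locked nucleic acid, a modified oligonucleotide that pairs tightly with its target, and it is directed against miR-205, a microRNA that is abundant in basal epithelial cells. LNA-Scr is a scrambled oligomer and served as the control. Each group held 3 samples, LNA-Scr replicates A, B and C and LNA-205 replicates D, E and F, and each sample was hybridised to 1 single-colour Illumina bead array. Of 48799 probes with values, between 12585 (LNA-Scr replicate C) and 14195 (LNA-Scr replicate A) were above background on an array at a detection p under 0.01, and the median probe intensity lay between 217 and 226.5. The comparison of LNA-205 with LNA-Scr asks which transcripts of prostate epithelial cells differ when miR-205 is silenced.

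The arrays do not read mature miR-205. The probe for MIR205HG, the transcript from which miR-205 is cut, was not well above background on any of the 6 arrays, so no level or fold is given for it. That transcript would not report the silencing in any case, because the oligomer acts on the mature microRNA. Silencing was therefore not checked by these measurements.

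MCCC2, which encodes a subunit of methylcrotonoyl-CoA carboxylase, a mitochondrial enzyme of leucine breakdown, fell in LNA-205 cultures. Its normalized log2 intensity was 9.77 ± 0.22 (SD, n = 3) in LNA-Scr and 8.05 ± 0.24 (SD, n = 3) in LNA-205, and the 3 values of each group did not overlap. The log2 difference was −1.72 (SE 0.16, 95% interval −2.09 to −1.36), a 3.30-fold lower level, with a limma adjusted p of 0.0445. It was the 1 feature past the threshold among 10803 tested, and 0 features passed in the higher direction. The next smallest adjusted p was 0.350. At an unadjusted limma p under 0.05 there were 677 features, 345 higher and 332 lower in LNA-205, against 540.15 expected by chance. The groups did not overlap for 1313 features, or 12.2%, where chance gives 10% on average for 3 against 3. Such counts vary widely between groupings. Other splits of the 6 arrays into 3 and 3 gave 865 to 1265 features without overlap. They gave 371 to 651 features at an unadjusted limma p under 0.05. The MCCC2 call was lost without a detection filter (adjusted p = 0.180), with the mean of a gene's probes (0.0512) and with every probe as its own feature (0.0646). It was also lost with any 1 of the 6 arrays left out (adjusted p from 0.0969 without LNA-Scr replicate A to 0.335 without LNA-Scr replicate B).

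The other genes with the smallest p in each direction did not pass the test. The 5 with higher values in LNA-205 were FERMT2, RHBDD3, C22orf23, KLK5 and CEBPA. FERMT2 encodes kindlin-2, an activator of integrins, and had a log2 difference of 0.70 (SE 0.10, adjusted p = 0.350). RHBDD3, of the rhomboid-like family, had a log2 difference of 0.82 (SE 0.12, adjusted p = 0.350). CEBPA, a transcription factor of epithelial and myeloid differentiation, differed by 0.69 (SE 0.12) and KLK5, a secreted serine protease of stratified epithelium, by 0.72 (SE 0.13). A second detected probe for KLK5 gave 0.40. C22orf23 was not well above background on any LNA-Scr array and was at least 1.32-fold higher in LNA-205. On the lower side, after MCCC2, stood GP1BA, TCF7L2, MAP1B and FOXC2. GP1BA, known as a platelet adhesion receptor subunit, had a log2 difference of −0.92 (SE 0.14) and TCF7L2, a transcription factor of Wnt signalling, one of −0.75 (SE 0.11), each with an adjusted p of 0.350. MAP1B, which encodes a microtubule-associated protein, and FOXC2, a transcription factor linked with mesenchymal transition, were detected on the 3 LNA-Scr arrays and on 0 LNA-205 arrays. Their levels were at least 1.05-fold and at least 1.22-fold lower in LNA-205, with adjusted p of 0.426 for both.

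**Figure D1:**
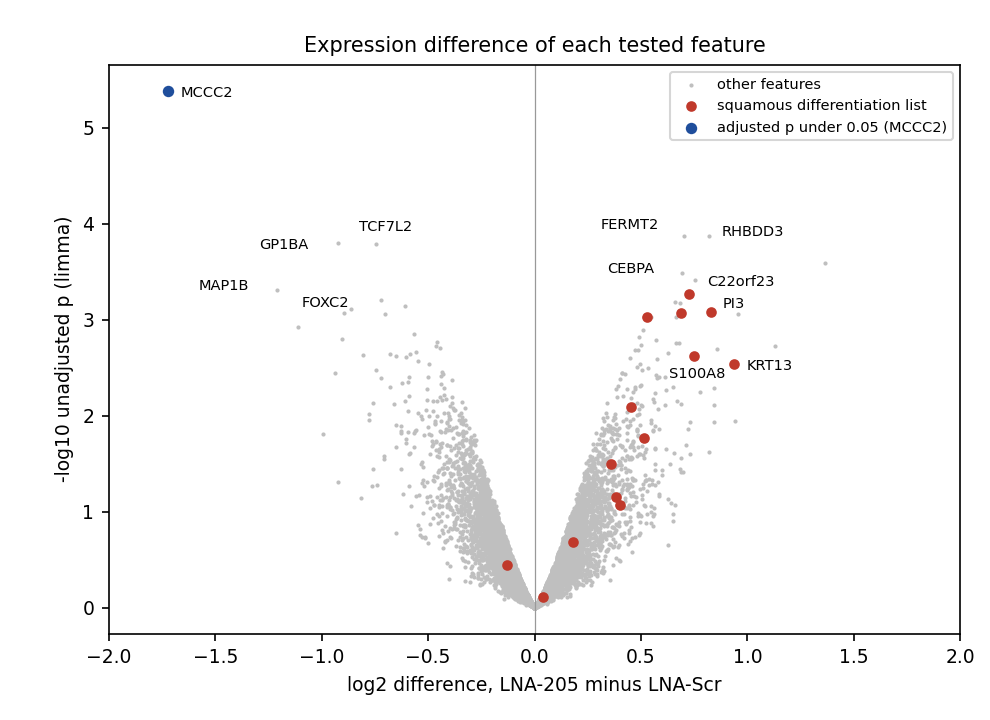
Each point is 1 of the 10803 tested features, with its log2 difference (LNA-205 minus LNA-Scr, n = 3 arrays each) on the x axis and −log10 of its unadjusted limma p on the y axis, and the genes of the squamous differentiation list in red. MCCC2 (blue) stands apart at −1.72, and 13 of the 14 red points lie to the right of 0.

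Genes of squamous differentiation rose as a group in LNA-205 cultures. Of the 29 genes of this list, 14 were measured, and 13 of them had higher values in LNA-205, with a mean log2 difference of 0.48 and a median of 0.48. Camera with the preset inter-gene correlation of 0.01 gave an adjusted p of 7.35e-12. The correlation estimated from these arrays was 0.12, and with it camera gave an adjusted p of 0.169. A preset correlation below that of the genes makes the p too small. Fry, which tests whether the genes move one way without comparing them with other genes, gave an adjusted p of 0.0319. Over all genes tested, 0 members passed. Adjusted over the list alone, 9 were higher and 0 lower.

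The members span several roles in the outer layers of stratified epithelium. KRT13, a keratin of suprabasal cells, went from 8.34 ± 0.38 to 9.28 ± 0.33 (SD, n = 3 each), a log2 difference of 0.94 (SE 0.22). PI3 (elafin), a secreted elastase inhibitor, differed by 0.83 (SE 0.16). The calcium-binding alarmins S100A8, S100A7 and S100A9 differed by 0.75 (SE 0.17), 0.69 (SE 0.13) and 0.45 (SE 0.13). Among cornified envelope genes, SPRR1A differed by 0.53 (SE 0.10), SPRR2D by 0.51 (SE 0.17), SPRR1B by 0.40 (SE 0.20) and TGM1, the transglutaminase that crosslinks the envelope, by 0.36 (SE 0.14). LCN2, an antimicrobial lipocalin, differed by 0.38 (SE 0.18) and CSTA, a protease inhibitor, by 0.18 (SE 0.13). KRT10 (0.04, SE 0.14) and CNFN (−0.13, SE 0.13) did not follow the group. Another 15 genes of the list, among them IVL, LORICRIN, FLG and KRT1, did not pass the detection filter. The mean of the 14 genes was higher on each LNA-205 array than on any LNA-Scr array, and a two-sided exact permutation test of the 6 array means gave p = 0.1, the smallest that 3 against 3 can give. Array means also did not overlap, with the same p, for the lists of reported miR-205 targets, basal epithelial genes, cholesterol synthesis and matrix proteases. S100A8, S100A9 and LCN2 are also expressed in myeloid cells, and the myeloid markers CD14 and CD68 differed by 0.31 and 0.20 without passing the test. A second CD68 probe detected on all 6 arrays gave 0.01, and PTPRC, ITGAM, CD163 and HLA-DRA did not pass the detection filter. Without the detection filter the mean log2 difference of the list was 0.25. Members of the SPRR, S100A and keratin families are similar in sequence, and cross-hybridisation between them was not tested.

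**Figure D2:**
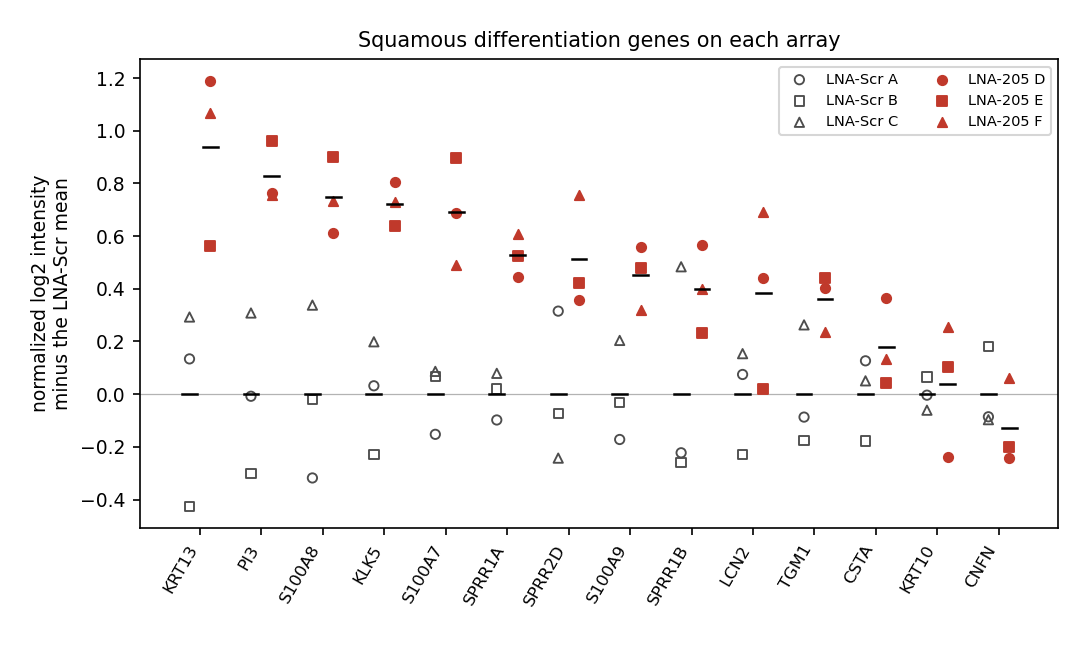
Normalized log2 intensity of each measured gene of the squamous differentiation list on each array, minus that gene's LNA-Scr mean (y axis). Open symbols are the 3 LNA-Scr arrays, filled symbols the 3 LNA-205 arrays and bars the group means, which run from 0.94 for KRT13 to −0.13 for CNFN in LNA-205.

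Interferon response genes passed camera with the preset correlation and neither of the other list tests. Of 40 genes, 34 were measured and 30 had higher values in LNA-205, with a mean log2 difference of 0.11 and a median of 0.14. Camera gave an adjusted p of 0.00509 with the preset correlation of 0.01. With the estimated correlation of 0.36 it gave 0.930, and the fry adjusted p was 0.882. No member passed over all genes tested or adjusted over the list alone. RSAD2 (viperin), an antiviral enzyme, had a log2 difference of 0.60 (SE 0.24), and IFITM3, a restriction factor for virus entry, one of 0.17 (SE 0.10). IFIT5, which binds viral RNA, went against the group at −0.76 (SE 0.21) and was detected on 1 of the 3 LNA-205 arrays. The array means of the list overlapped between the groups (two-sided exact permutation p = 0.4). The call was lost without LNA-Scr replicate A (mean 0.04, adjusted p = 0.373) and without LNA-205 replicate E (mean 0.04, adjusted p = 0.447).

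Matrix proteases and their inhibitors were the third list past the threshold. Of 26 genes, 15 were measured and 11 had higher values in LNA-205, with a mean log2 difference of 0.13. Camera gave an adjusted p of 0.0364 with the preset correlation of 0.01, and of 0.517 with the estimated correlation of 0.07. None passed over all genes or adjusted over the list alone. TIMP2, an inhibitor of metalloproteinases, had a log2 difference of 0.41 (SE 0.10), but a second detected probe for TIMP2 gave −0.30. MMP14, a membrane-bound metalloproteinase that cleaves pericellular collagen, differed by 0.37 (SE 0.15) and TIMP1 by −0.05 (SE 0.10). The call was lost with probes detected on all 6 arrays (adjusted p = 0.0935), with the mean of a gene's probes (mean log2 difference 0.07, adjusted p = 0.454) and with every probe as its own feature (0.05, adjusted p = 0.382). It was also lost without LNA-Scr replicate A (adjusted p = 0.0508), LNA-Scr replicate B (0.207) or LNA-205 replicate E (0.347).

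Transcripts reported elsewhere as miR-205 targets did not pass the test as a group. Of 24 such genes, 12 were measured, and 9 of these had higher values in LNA-205, with a mean log2 difference of 0.09 (camera adjusted p = 0.260, fry adjusted p = 0.0552). Its array means were higher on each LNA-205 array than on any LNA-Scr array (two-sided exact permutation p = 0.1). No member passed over all genes or adjusted over the list alone. VEGFA, an angiogenic growth factor, had a log2 difference of 0.39 (SE 0.19) and MED1, a subunit of the Mediator complex, one of 0.31 (SE 0.10). LYN, a Src-family kinase, differed by 0.24 (SE 0.14), LAMC1 by 0.22 (SE 0.12), the receptor ERBB3 by 0.15 (SE 0.14) and the phosphatase INPPL1 by 0.10 (SE 0.15). The 3 lower members were ITGA5 at −0.23 (SE 0.14), BCL2L2 at −0.12 (SE 0.11) and SRC at −0.08 (SE 0.11). For ITGA5 and BCL2L2 only the brightest probe is given. ZEB1, ZEB2 and PRKCE were not well above background on any array, and E2F1 was above it on 1 of the 6. Without the detection filter the mean log2 difference of the list was 0.03.

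Basement membrane genes did not differ as a group. Of 30 genes, 14 were measured, 7 with higher and 7 with lower values in LNA-205. The mean log2 difference was −0.02 and the camera adjusted p 0.991, with none past the threshold over all genes or adjusted over the list alone. Camera's direction was upward while the mean was below 0. The list was chosen knowing that a role of miR-205 in basement membrane deposition has been published for such cells. LAMB3, a chain of laminin-332, had a log2 difference of −0.12 (SE 0.14), LAMA5 one of 0.13 (SE 0.14), COL4A1 one of −0.03 (SE 0.14) and COL4A2 one of 0.06 (SE 0.23). The integrin and hemidesmosome list (14 of 20 measured, mean −0.03, camera adjusted p = 0.856) did not pass either. ITGA6 and ITGB4, the hemidesmosomal pair, had log2 differences of −0.11 (SE 0.16) and 0.03 (SE 0.10), and a second detected ITGB4 probe gave −0.16.

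Lists of epithelial identity did not pass camera with the processing used here. In the basal epithelial list 9 of 11 measured genes had higher values in LNA-205, with a mean log2 difference of 0.11 (camera adjusted p = 0.0644, fry adjusted p = 0.0319). Camera called the basal epithelial list without background correction, with probes detected on all 6 arrays, with the mean of a gene's probes and with every probe as its own feature. KRT16 had a log2 difference of 0.36 (SE 0.12) and TRIM29 one of 0.26 (SE 0.10). The abundant basal keratins KRT5 and KRT14 had differences of 0.12 (SE 0.10) and 0.03 (SE 0.10). In the luminal prostate list, 6 of 20 genes were measured (mean −0.01, camera adjusted p = 0.991). KRT8 differed by 0.04 (SE 0.11) and KRT18 by −0.28 (SE 0.18), with 0.05 from a second detected KRT18 probe. The epithelial junction list (20 measured, mean 0.02, adjusted p = 0.856) included CDH1 (E-cadherin) at 0.06 (SE 0.11). The mesenchymal list (16 measured, 11 higher and 5 lower, mean 0.03, adjusted p = 0.837) included VIM (vimentin) at 0.07 (SE 0.11). FN1 (fibronectin) was not well above background on any array. The mean near 0 hides members that moved in opposite directions. The mixed form of fry, which counts changes either way, gave an adjusted p of 0.00630 for this list and for the housekeeping list. Adjusted over the list alone, 1 mesenchymal gene passed, FOXC2, on the lower side.

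None of the remaining lists passed camera with the processing used here. Cholesterol synthesis genes had lower values in 13 of 18 cases, with a mean log2 difference of −0.11 (camera adjusted p = 0.0732, fry adjusted p = 0.104). Camera called this list with the mean of a gene's probes and with every probe as its own feature. TM7SF2, a sterol reductase, had a log2 difference of −0.68 (SE 0.18) and MSMO1, a sterol oxidase, one of −0.20 (SE 0.11), although a second detected MSMO1 probe gave 0.01. The G2/M list had all 30 genes measured, 16 higher and 14 lower, with a mean of 0.04 and a camera adjusted p of 0.577. CDC20, its member with the smallest limma p, differed by −0.33 (SE 0.12). UBE2C differed by −0.04 (SE 0.10), with 0.09 from a second detected UBE2C probe. The DNA replication list had a mean of 0.02 (adjusted p = 0.921). Mean log2 differences were 0.04 for p53 targets (adjusted p = 0.837), 0.07 for ER stress genes (0.693) and 0.12 for inflammatory cytokines (0.577). TGF-beta and YAP targets had a mean of 0.03 (adjusted p = 0.921) and immediate early genes one of 0.02 (0.991). The microRNA machinery had a mean of −0.01 (adjusted p = 0.991) and housekeeping genes one of 0.01 (0.921). The sign of camera or of the median opposed that of the mean for the immediate early, microRNA machinery and housekeeping lists. Markers of other cell types were mostly undetected. Of 14 stromal fibroblast genes 1 was measured, of 9 neuroendocrine genes 1 and of 14 immune and endothelial genes 2, too few to test as lists. Each had a higher mean in LNA-205 and none passed over all genes tested. The log2 difference was 0.59 (SE 0.28) for INSM1, a neuroendocrine transcription factor detected on 3 of the 6 arrays, 0.31 (SE 0.17) for CD14 and 0.20 (SE 0.11) for CD68, both myeloid markers, and 0.05 (SE 0.13) for COL5A1, a fibrillar collagen chain. A second probe for CD68 detected on all 6 arrays gave 0.01.

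**Figure D3:**
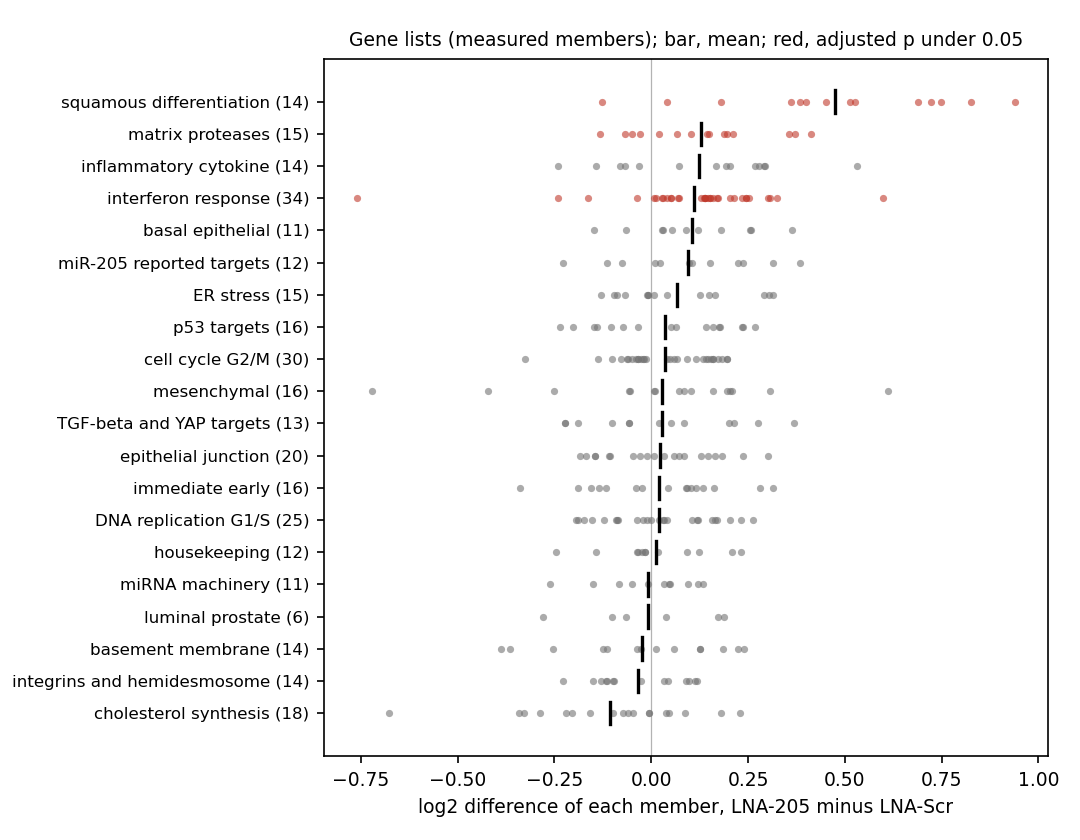
Log2 difference (LNA-205 minus LNA-Scr) of each measured member of the 20 tested gene lists on the x axis, with the number measured in brackets. Vertical bars are list means, from 0.48 for squamous differentiation to −0.11 for cholesterol synthesis, and red points belong to the 3 lists past a camera adjusted p of 0.05 with the preset correlation.

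Pairs of arrays from the same group differed about as much as pairs from different groups. The SD of the log2 difference over detected probes was between 0.291 and 0.330 for pairs within a group and between 0.306 and 0.330 for pairs across groups. The second principal component (22.4% of the variance) ran from −15.0 to 0.942 over the LNA-Scr arrays and from 2.96 to 15.2 over the LNA-205 arrays, without overlap. Chance gives such a separation in 10% of cases for any 1 component with 3 against 3 arrays. The median absolute log2 difference of the 10803 features was 0.10, against a median SE of 0.13. Simulated data had variances drawn from limma's fit to these arrays, normal noise and 200 changed features. There, genes changed by a log2 value of 1 were called in 86.6% of cases and those changed by 0.5 in 15.6%. The adjustment is stricter where fewer features change, so a log2 value of 1 could be missed more often in these data. GP1BA, at −0.92, had a limma adjusted p of 0.350. Differences of about 0.5 in single genes were mostly not detectable with 3 arrays per group. The labels say that cells were transfected in triplicate, without saying whether the cultures were grown apart. The p-values set differences against the spread between these samples, and cultures not grown apart could make them too small.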

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

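MCCC2 had the smallest p under each of the 17 alternative fits, with log2 differences from −1.81 to −1.24. The count of features past the threshold fell from 1 to 0 without a detection filter (39557 features tested), with the mean of a gene's probes, with every probe as its own feature (13423 tested), at an adjusted p under 0.01 and in each of the 6 fits that leave out 1 array. It rose to 3 with eBayes trend and robust (MCCC2, FERMT2 at an adjusted p of 0.0206 and PI3 at 0.0196, and for PI3 the adjusted p ran from 0.312 to 0.841 over the fits that leave out 1 array). More tests account for part of the loss without a filter or with every probe. Fewer arrays may account for part of the loss when 1 is left out, but this was not tested separately, nor were other causes. The squamous list was called in each of the 17 fits and by fry, with means from 0.25 to 0.55, and not by camera with an estimated correlation (0.48). Lists past the threshold, 3 in the report, numbered 4 without background correction (basal epithelial gained), and with the mean of probes or every probe (basal epithelial and cholesterol synthesis gained, matrix proteases lost), 3 with detection on all arrays (basal epithelial in place of matrix proteases), 2 by fry (squamous and basal epithelial), between 1 and 3 with 1 array left out, and 0 with an estimated correlation. The interferon list (mean 0.11) was not called with an estimated correlation or by fry, and its mean ran from 0.0381 to 0.18 over the fits that leave out 1 array. The matrix protease list (mean 0.13) was not called by these either, nor with detection on all arrays (0.10), the mean of probes (0.0656) or every probe (0.0525), and ran from 0.0947 to 0.16 with 1 array left out. The basement membrane mean turned positive without a filter (0.0172), with detection on all arrays (0.0346) and with every probe (0.0375), and ran from −0.0812 to 0.0195 with 1 array left out. Of 1060 recomputed values for 64 named genes, 19 changed sign, all of genes that were not called. Over all alternative fits, the value nearest to 0 was −0.53 for GP1BA, 0.36 for CEBPA and 0.49 for RHBDD3. It was −0.40 for TM7SF2 and 0.35 for KLK10. With 1 array left out, log2 differences ran from −0.0658 to 0.18 for KRT10, −0.23 to 0.0156 for LAMB3, −0.12 to 0.12 for COL4A1, −0.10 to 0.36 for COL4A2, −0.25 to 0.0454 for ITGA6, −0.0154 to 0.10 for CDH1, −0.00803 to 0.13 for VIM, −0.0263 to 0.0784 for KRT14, −0.0284 to 0.0957 for KRT8, −0.0355 to 0.14 for COL5A1 and −0.0400 to 0.22 for INPPL1. Median scaling gave −0.0158 for ITGB4, −0.00688 for VIM and −0.0184 for KRT14, and the mean of probes −0.0621 for ITGB4. Sizes of other genes moved without a change of sign. With 1 array left out, RSAD2 ran from 0.31 to 0.80, IFIT5 from −0.92 to −0.50 and VEGFA from 0.20 to 0.51. LYN ran from 0.10 to 0.32, ERBB3 from 0.0351 to 0.23, LCN2 from 0.23 to 0.57 and CSTA from 0.0880 to 0.25. SPRR1B ran from 0.27 to 0.64, KLK10 from 0.41 to 0.88, MSMO1 from −0.26 to −0.11 and CD14 from 0.14 to 0.49. MCCC1 ran from −0.27 to −0.0209 and IVD from −0.33 to −0.14. The slide as a block and the seed match test with its alternatives were not run. Signal over background limits the dim probes: 27.5% of probes passed the filter, and MAP1B, FOXC2, C22orf23 and ALOXE3 have only a bound in 1 group and no value in the fits that leave out 1 array of the other group. INSM1 has none without an array that detects it. CEBPA, SPRR2D, MMP14 and KLK10 were above background on 2 of the 3 LNA-Scr arrays. GP1BA, TM7SF2 and CNFN were above it on 2 of the 3 LNA-205 arrays. The differences of these genes rest in part on values near background.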

Other observations

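The tests of cell division, of squamous genes outside the fixed list and of branched-chain amino acid breakdown were chosen after the results they bear on were seen, and the bound for cell division was set with the mean of the G2/M list already known. The gene lists of the squamous and branched-chain tests were written from textbook knowledge before the values of their members were looked at.

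Squamous genes outside the fixed list went both ways in LNA-205. A second list of 70 genes, none of them on the first, had 25 measured members, 15 higher and 10 lower in LNA-205, with a mean log2 difference of 0.11 (camera p = 0.146, and p = 0.403 with an estimated correlation). Its array means overlapped between the groups. IL1RN, the antagonist of interleukin-1 receptor, had a log2 difference of 0.68 and was the 1 member past the threshold adjusted over the list alone (adjusted p = 0.0437). KLK10, a secreted protease, differed by 0.69 and SLPI, a secreted protease inhibitor, by 0.57. KLK10 was above background on 2 of the 3 LNA-Scr arrays. In the other direction, TGM2, a transglutaminase, differed by −0.59, and ALOXE3, a lipoxygenase of the epidermal barrier, was detected on the 3 LNA-Scr arrays and on 0 LNA-205 arrays, at a level at least 1.27-fold lower in LNA-205. None of these passed over all genes tested. Whether the shift of the first list may extend to other squamous genes stays open, since the mean of 0.11 lay within 2 standard errors (SE 0.07) of the bound of 0.1 set for it.

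The upward shift of the squamous list (mean log2 difference 0.48) does not rest on a single array, since the lowest mean over the 6 fits that leave out 1 array was 0.42, above the bound of 0.3. The background step or normalization does not account for it either: over 5 other choices the lowest mean was 0.38, from the authors' processed values. Squamous genes can rise when epithelial cells stop dividing. The G2/M list had 16 genes higher and 14 lower, with a mean log2 difference of 0.0354 (SE of the array scores 0.0167). The DNA replication list had a mean of 0.02. Neither mean was below 0. The bound of −0.1 for the G2/M list was set with its mean known, so staying above it decides nothing. Fewer dividing cells stay open as an explanation, because members of the G2/M list went both ways. Chance stays open too, since 10 splits of the 6 arrays are too few for a share under 0.05, and the absolute mean was at most 0.29 in the other 9. Silencing of miR-205 remains a candidate explanation, as do culture density and cross-hybridisation between related probes, none of which was tested.

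The lower MCCC2 signal was weighed in the same way. The log2 difference nearest to 0 was −1.59 over the 6 fits that leave out 1 array and −1.24 over 5 other background steps and normalizations, both beyond the bound of −1. The rest of its pathway did not go with it: 22 other measured genes of branched-chain amino acid breakdown had a mean log2 difference of −0.0306 (SE 0.0184), 11 higher and 11 lower, which speaks against a decrease of the whole pathway by 0.3. MCCC1, the partner subunit, had −0.13, IVD, the enzyme before it, −0.22 and BCAT2, a mitochondrial transaminase, −0.20, none of them past the threshold. Pairing of the LNA-205 oligomer with the MCCC2 transcript and an effect of miR-205 on it were not tested, and the value rests on 1 probe.

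The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1 feature past the threshold, as did 1 of the 10 splits counting the real one, and the highest of the others gave 0. For gene lists past the camera threshold with the preset correlation, the real split gave 3, 3 of the 10 splits gave as many, and the highest of the others gave 4. Features at an unadjusted p under 0.05 numbered 677 in the real split and at most 651 in another.

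Detection differed in one direction more often than in the other. There were 39 probes above background on all 3 LNA-Scr arrays and on no LNA-205 array, and 6 probes with the opposite pattern. In 2 of the other 9 splits the larger of these counts was higher than 39, at 106 and 123, so such counts also arise between arrays mixed from both groups. The number of detected probes ran from 12585 to 14195 in LNA-Scr and from 12638 to 13366 in LNA-205. The first principal component (23.3% of the variance) set LNA-Scr replicate C apart from the other arrays. On the second (22.4%) the groups did not overlap. There, LNA-Scr replicate C (0.942) lay closer to LNA-205 replicate F (2.96) than to LNA-Scr replicates A (−13.5) and B (−15.0). The inflammatory cytokine list was lowest in LNA-Scr replicate A, 0.39 below the LNA-Scr mean.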
